A study of Pseudomonas putida with 36 samples.

How the data were processed

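The labels describe 36 libraries of wild-type Pseudomonas putida KT2440 from a glucose minimal medium bioreactor, 3 for each of 12 combinations of sampling position and time. Per the labels' protocols, RNA was extracted with phenol and chloroform after lysis, ribosomal RNA was depleted, and libraries were sequenced on an Illumina instrument as paired 150 base reads, with a stated 20M reads per library. Samples were grouped by the position and time in their titles, and the letters A, B and C in the titles gave the replicate.

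The values are RPKM, per the file header, and were made by the authors before deposit. The submitters' processing notes name FastQC, cutadapt, Bowtie2, SAMtools and featureCounts, without versions. The genome build, the annotation, the method that predicted the ncRNAs, the rule behind the 3 classes, the use of strand in counting, and whether the RPKM total counts all mapped or only assigned reads are not given in the sources used here. The deposited table has 1 RPKM column per group, 12 in all, and how the 3 libraries of a group were combined is likewise not given. Each value is therefore a pooled or averaged value of its group and is printed without SD or n. Start, end, strand, length and class were used as the authors list them, and length equalled end minus start plus 1 for all 725 ncRNAs. RPKM divides by length, so ncRNAs of different lengths are on 1 scale, and it divides by a total, so abundant RNAs elsewhere can lower the other values of a column.

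The designs fixed before the data were examined assumed values per library. They called for moderated tests over replicates, tests over all times or ports together, a test of the interaction, set tests, a replicate block and the omission of each replicate in turn. With 1 value per group none of these could be fitted, and no p-value was computed. Each comparison was instead described by the difference of log2(RPKM + 1) between columns, called at least 2-fold where it reached 1 in size. A fold change on this scale understates the change of ncRNAs with low values. The 11 pairwise comparisons were each later time at S against 0 min, and P1, P3 and P5 against S at 15 min and at 25 h. The 5 results over several columns were counted by size as well, namely the largest of the 5 differences from 0 min, the largest port difference at 15 min, the same at 25 h, the largest change in a port difference between the times, and the mean difference between 25 h and 15 min over the 4 positions. An ncRNA had to have a mean of at least 1 RPKM, which removed 0 of the 725, since the lowest mean was 8.17.

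The rule for naming ncRNAs, fixed beforehand, asked for a test and for groups without overlap, so only its size part could be applied. It took up to 10 ncRNAs in each direction with a difference of at least 2-fold in the 4 main comparisons (S 15 min and S 25 h against 0 min, and P5 against S at both times), up to 3 in each direction in the others, the 5 largest for each result over several columns, and the 10 with the highest mean. Other ncRNAs named were chosen after their values were seen, namely neighbours of named ones, the trans-encoded members listed, the 5 ncRNAs with 1 shared profile, PP_nc190 and PP_nc162 at P5, and the 3 ncRNAs whose port difference changed at P5. Of the gene lists fixed beforehand, known small RNAs were to be matched by name, and 0 matched because the table uses serial names. Lists by neighbouring gene were not used here, because the gene table at hand belongs to another strain of the species. The lists by class were used.

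For each class and comparison the median log2 fold change was placed among the medians of 10000 random lists of the same size, drawn from all 725 ncRNAs and matched on the decile of mean RPKM. The overlap of 2 lists was set beside the number that independent lists would share. The random lists and this number treat the ncRNAs as separate entries. Same-strand neighbours moved together at P5 25 h, so the contrast with random or independent lists can be overstated. Whole-read steps in the RPKM values were searched for in each column, and 25.3% to 31.3% of the lowest values came within 0.1 of a whole number of reads at the best depth. The same search on values moved at random by up to 20%, 20 sets per column, gave 21.3% to 35.3%, and no column scored above all of its random sets. With whole reads put in at a depth of 20M the search found 100% of them whole. The mapped depth behind each value is therefore unknown, and no counting interval is given. The share of reads in ncRNAs was the sum of RPKM times length in kilobases.

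Alternatives listed beforehand and run here were pseudocounts of 0.1 and 5, no filter on low values, a minimum mean of 5, median-of-ratios scaling and quantile normalisation of the deposited values. Added after seeing the data were the pairs of later S columns as a yardstick of spread, the counts by size for the 5 results over several columns, the search for ncRNAs with 1 shared profile and their count as 1, the order of P1 and P3 between S and P5, the random sets of the whole-read search, and the removal of a length trend. Tested on simulated data for P5 25 h against S 25 h with all 725 ncRNAs, the counting step found 50 of 50 ncRNAs raised by 1.5 in log2 and 50 of 50 lowered by 1.5, and 0 of 525 unchanged ones. Of those shifted by 0.5 either way it called 0 of 50 each. The simulated noise was small beside these shifts, so this checks the arithmetic and the direction of the counts and not their reliability. Simulating unchanged groups that share a column was uninformative for the same reason and is not reported. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.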

Results

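RNA was sequenced from bioreactor cultures of wild-type Pseudomonas putida KT2440, a soil bacterium used as a laboratory and production host, grown on glucose in minimal medium. The labels list 36 libraries in 12 groups of 3. Position S was sampled at 0 min, 15 min, 1 h, 3 h, 9 h and 25 h, and positions P1, P3 and P5 at 15 min and 25 h. The labels do not spell out the position letters. As background, scale-down bioreactors of this kind couple a stirred tank to a plug-flow tube with numbered ports, and the numbers are read here only as an order of ports. The series' stated purpose was to predict non-coding RNAs (ncRNAs) that matter for growth in the bioreactor, and its groups imply comparisons over time at S and between each port and S.

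The deposited table listed 725 predicted ncRNAs with the authors' names, PP_nc001 to PP_nc725, and 1 RPKM value (reads scaled to feature length in kilobases and to the library total) per group. The values are therefore the authors' group values and carry no SD. Without values per library there was no replicate check of any difference. A difference of at least 2-fold on the log2(RPKM + 1) scale is described below by its size alone. As a rough yardstick only, the log2 ratios between successive later S columns had an SD across the ncRNAs of 0.21 (3 h against 1 h), 0.23 (9 h against 3 h) and 0.12 (25 h against 9 h). Of the 725, 1 reached 2-fold in the 9 h against 3 h pair, at 1.01 in log2, and none in the other pairs. These spreads include any real change between those times and are not replicate error. The labels state a nominal 20M reads per library, but the mapped depth behind each value is unknown, because no whole-read steps could be found in the values.

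The ncRNAs were 57 to 500 bases long, with a median of 279. The plus strand held 335 and the minus strand 390. The authors classed 411 as cis-encoded, 28 as trans-encoded and 286 as undefined. In common usage a cis-encoded RNA is transcribed at the locus it acts on and a trans-encoded RNA acts on targets elsewhere; the definitions behind these 3 classes are not given in the sources used here. Few ncRNAs lay in the middle of the coordinate range, with 18 starting between positions 3000001 and 3500000 and 22 between 3500001 and 4000000, against 89 between 1000001 and 1500000. Another 20 started after 6000000, a stretch that is short because the last ncRNA ends at 6181791. The table has no chromosome column, and the genome build behind the coordinates is not given in the sources used here.

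A few ncRNAs held much of the signal. PP_nc235 (cis-encoded, 1512697 to 1513046, minus strand) had a mean of 48719 RPKM over the 12 groups, and PP_nc608 (cis-encoded, 5338288 to 5338591, minus strand) 31499 RPKM. Together they took 34.8% to 46.2% of the ncRNA reads of a group, least at S 1 h and most at P5 25 h. Their own ranges were narrow: the highest group value was 1.63 times the lowest for PP_nc235 and 1.47 times for PP_nc608. Next came PP_nc162 at a mean of 8352 RPKM, PP_nc377 at 4282, PP_nc613 at 1801, PP_nc056 at 1624, PP_nc190 at 1587, PP_nc276 at 1497, PP_nc682 at 1428 and PP_nc704 at 1334. Of these, PP_nc190 (1256906 to 1257201, plus strand) ranged most, from 323 RPKM at P5 25 h to 2326 at S 15 min. All 725 ncRNAs together took 6.54% to 7.32% of the reads in the RPKM denominator, so their summed share differed little between groups. Within that sum PP_nc235 and PP_nc608 took 36.8% at S and 43.6% at P5 at 15 min, and 36.4% and 46.2% at 25 h. The other ncRNAs thus held a smaller part of the sum at P5 than at S.

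The first question was how the ncRNAs at S differed from 0 min at each later time. At 15 min 32 ncRNAs were at least 2-fold higher and 37 at least 2-fold lower than at 0 min. PP_nc364 (cis-encoded, 2531238 to 2531497, minus strand) went from 20.3 to 102 RPKM, a log2 fold change of 2.28. PP_nc604 (trans-encoded, 5312771 to 5313119, plus strand) went from 113 to 512 RPKM, and PP_nc026 (trans-encoded, 171018 to 171318, minus strand) from 156 to 512 RPKM. PP_nc675 stood at 82.4 against 24.8 RPKM and the abundant PP_nc118 (undefined class, 839836 to 840075, plus strand) at 1330 against 426 RPKM. The other 5 of the 10 largest, PP_nc648, PP_nc104, PP_nc219, PP_nc406 and PP_nc277, had log2 fold changes of 1.43 to 1.62.

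In the other direction at 15 min, PP_nc627 (cis-encoded, 5377712 to 5378126, plus strand) was at 60.9 RPKM against 238 at 0 min, a log2 fold change of -1.95. PP_nc458 was at 119 against 432 RPKM, PP_nc343 at 91.2 against 302, PP_nc165 at 133 against 436 and PP_nc014 at 43.4 against 139. PP_nc400, PP_nc164, PP_nc667, PP_nc166 and PP_nc643 followed, with log2 fold changes of -1.38 to -1.55. PP_nc164, PP_nc165 and PP_nc166 are neighbours on the plus strand between 1137815 and 1141078, and 8 of these 10 were cis-encoded.

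Fewer ncRNAs reached 2-fold from 0 min at later times. At 1 h 18 ncRNAs were at least 2-fold higher and 25 lower, led by PP_nc364 (71.3 RPKM), PP_nc406 (220) and PP_nc118 (1088) above and by PP_nc343 (76.8), PP_nc164 (104) and PP_nc165 (150) below. At 3 h 13 were higher and 8 lower; with either other scaling this split was even, 12 and 12 or 11 and 11. PP_nc597, PP_nc598 and PP_nc406 led upward at 3 h, and PP_nc343, PP_nc369 and PP_nc165 downward. At 9 h and at 25 h 4 were higher and 2 lower. With median-of-ratios scaling the 9 h split was 3 and 4, with quantile normalisation 5 and 4, and quantile normalisation gave 4 and 1 at 25 h, of which 4 in all were among the 6. Over all 5 later times 84 ncRNAs reached 2-fold at least once.

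The 6 ncRNAs at least 2-fold from 0 min at 25 h were few enough to list. PP_nc597 (cis-encoded, 5260991 to 5261316, plus strand) was at 200 RPKM against 38.6, and its neighbour PP_nc598 (5261318 to 5261557, plus strand) at 49.8 against 9.41. These neighbours went up along the series, PP_nc597 from 87.4 RPKM at 15 min through 91.1, 126 and 196 to its 25 h value. PP_nc406 (undefined class, 3276375 to 3276798, plus strand) was at 201 against 78.5 RPKM and had been at 215 by 15 min. PP_nc364 was at 44.8 against 20.3 RPKM, down from 102 at 15 min. PP_nc132 (945377 to 945653, plus strand) was at 49.0 against 110 RPKM and PP_nc343 at 150 against 302. PP_nc364 and PP_nc343 lay close to the 2-fold limit and fell short of it with a pseudocount of 5 (0.98 and -0.99) and with quantile normalisation (0.86 and -0.97). At 9 h PP_nc132 and PP_nc131 were the 2 lower ones, PP_nc131 at -1.01 in log2, or -0.97 with a pseudocount of 5. All 4 ncRNAs higher at 25 h were also among those higher at 15 min and both lower ones among those lower at 15 min; independent lists would share 0.18 and 0.1. These comparisons share the 0 min column, and part of the overlap may come from it.

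**Figure D1:**
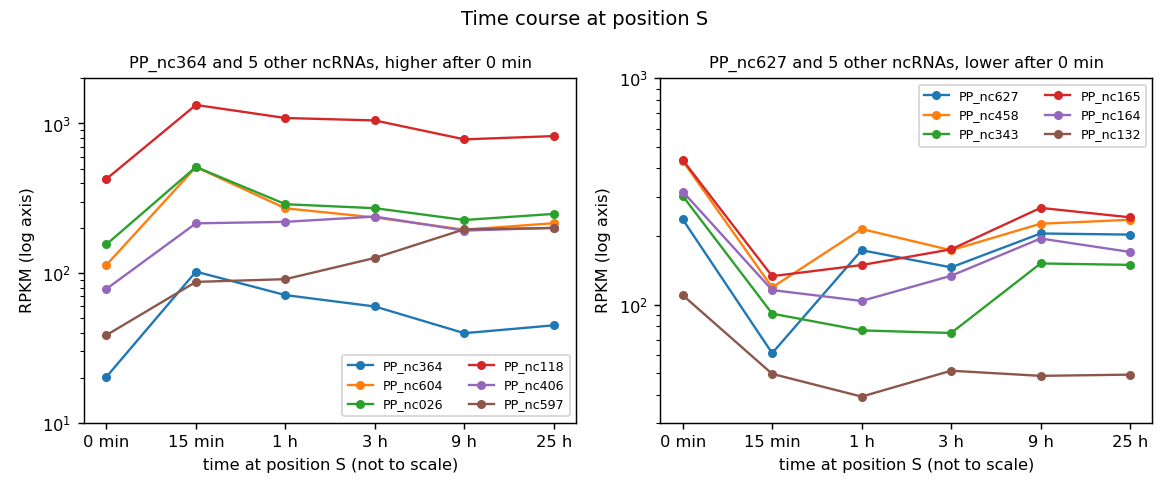
RPKM (log axis) of 12 named ncRNAs at position S from 0 min to 25 h (times not to scale), 1 point per group value, no replicates. Left, ncRNAs higher after 0 min, such as PP_nc364 with 20.3 RPKM at 0 min, 102 at 15 min and 44.8 at 25 h; right, ncRNAs lower after 0 min, such as PP_nc627 with 238, 60.9 and 204 RPKM.

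Followed as sets, the ncRNAs picked at 15 min lay nearer to 0 min later on. The 32 higher ones had a median log2 fold change of 1.34 at 15 min, 1.01 at 1 h, 0.85 at 3 h, 0.65 at 9 h and 0.67 at 25 h, and all 32 stayed above 0 at each time. The 37 lower ones had medians of -1.20, -0.89, -0.81, -0.44 and -0.47, and all stayed below 0. Because the sets were chosen on the 15 min value, that value is expected to be the most extreme. All these comparisons also share the 0 min column used in the choice, which by itself tends to keep a set on its side, so the signs at later times are not separate evidence.

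The second question was how the ports differed from S at 15 min. The number of ncRNAs at least 2-fold from S went from 3 at P1 (2 higher, 1 lower) to 31 at P3 (4 higher, 27 lower) and 96 at P5 (10 higher, 86 lower), and 25 of those at P5 were at least 4-fold lower. The 3 at P1 were PP_nc715 and PP_nc010 above S and PP_nc202 below; both other scalings gave 3 higher and none lower there, and a pseudocount of 5 took PP_nc010 from 1.01 to 0.98. The P5 split depended on the scaling, with 19 higher and 68 lower under median-of-ratios scaling and 24 and 47 under quantile normalisation. The median over all ncRNAs was -0.11 in log2 at P5, which median-of-ratios scaling moved to 0.04.

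PP_nc493 (undefined class, 4516944 to 4517078, minus strand) had the lowest log2 fold change at P5 at 15 min, -3.79, with 161 RPKM at S, 97.1 at P1, 42.1 at P3 and 10.7 at P5. PP_nc202 (trans-encoded, 1325190 to 1325430, minus strand) went from 782 RPKM at S to 56.4 at P5, and PP_nc370 (undefined class, 2585720 to 2586073, minus strand) from 192 to 14.9. PP_nc026 went from 512 to 45.5 RPKM, PP_nc335 (undefined class, 2241524 to 2241793, minus strand) from 342 to 31.1, PP_nc118 from 1330 to 140, PP_nc604 from 512 to 56.7 and PP_nc364 from 102 to 13.7. PP_nc028 (trans-encoded, 176496 to 176748, minus strand) went from 723 to 112 RPKM. PP_nc358 completed the 10, at 2.12 RPKM against 16.3, among the lowest values of the table, and its log2 fold change of -2.47 was -1.58 with a pseudocount of 5 and -0.97, under 2-fold, with quantile normalisation. PP_nc335, PP_nc370 and PP_nc118 also led the 27 lower at P3, where they stood at 57.9, 33.6 and 282 RPKM.

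The 10 ncRNAs higher at P5 at 15 min were PP_nc715, PP_nc180, PP_nc406, PP_nc598, PP_nc597, PP_nc595, PP_nc248, PP_nc292, PP_nc031 and PP_nc393. PP_nc180 (cis-encoded, 1169697 to 1170176, plus strand) went from 183 RPKM at S to 758 at P5, PP_nc406 from 215 to 803 and PP_nc597 from 87.4 to 275. PP_nc715 (cis-encoded, 6084936 to 6085028, minus strand) had its highest value at P3, with 9.64 RPKM at S, 31.1 at P1, 71.7 at P3 and 53.3 at P5. The remaining members from PP_nc595 on had log2 fold changes of 1.01 to 1.19, of which PP_nc292 and PP_nc393 fell under 2-fold (0.99 and 0.94) with a pseudocount of 5.

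**Figure D2:**
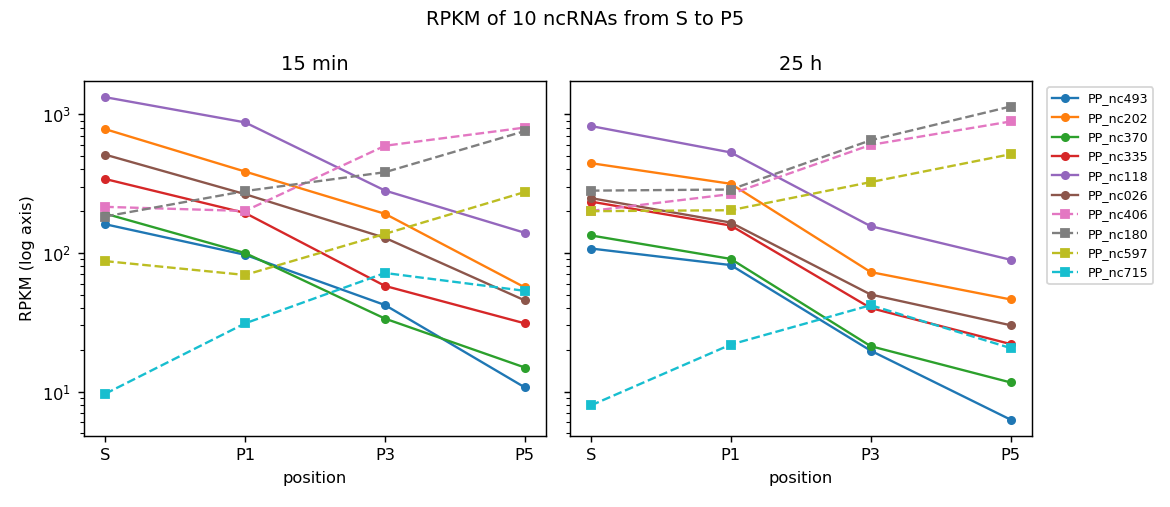
RPKM (log axis) of 10 named ncRNAs at positions S, P1, P3 and P5, at 15 min (left) and 25 h (right), 1 point per group value, no replicates; solid lines are ncRNAs lower at P5, dashed lines ncRNAs higher at P5. PP_nc493 stood at 161 RPKM at S and 10.7 at P5 at 15 min, PP_nc406 at 215 and 803, and PP_nc715 peaked at P3.

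At 25 h the comparison of the ports with S gave 1 ncRNA at least 2-fold apart at P1, PP_nc715, then 41 at P3 (3 higher, 38 lower) and 149 at P5 (10 higher, 139 lower), 40 of the latter at least 4-fold lower. Median-of-ratios scaling gave 35 at P3 and 117 at P5, with 14 higher and 103 lower at P5. Quantile normalisation, which forces equal distributions, gave 24 at P3 and 95 at P5, with 25 higher and 70 lower at P5. The numbers thus depend on the scaling, and the cause of the drop was not tested. The median over all ncRNAs was -0.18 at P5 as deposited, 0.03 with median-of-ratios scaling and 0.13 with quantile normalisation.

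PP_nc493 again had the lowest log2 fold change at P5, -3.90, at 6.28 RPKM against 108 at S. PP_nc316 (cis-encoded, 2035637 to 2035944, plus strand) stood at 11.3 against 130 RPKM, PP_nc370 at 11.7 against 134, PP_nc335 at 22.0 against 235, PP_nc202 at 46.2 against 444 and PP_nc118 at 89.3 against 824. PP_nc111 was at 22.9 against 214 RPKM, PP_nc077 at 53.9 against 445, PP_nc026 at 30.1 against 249 and PP_nc136 at 8.52 against 68.0. PP_nc370, PP_nc202 and PP_nc335 led at P3 as well. PP_nc162 (cis-encoded, 1123448 to 1123746, plus strand), next to PP_nc235 and PP_nc608 in mean RPKM, was at 2798 RPKM at P5 against 9635 at S.

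Higher at P5 at 25 h were PP_nc406 (888 against 201 RPKM), PP_nc180 (1138 against 282), PP_nc248, PP_nc597 (515 against 200), PP_nc715, PP_nc120, PP_nc319, PP_nc279, PP_nc598 and PP_nc179. PP_nc179 (1168884 to 1169195) and PP_nc180 are neighbours on the plus strand, as are PP_nc597 and PP_nc598. PP_nc319, at 182 against 81.3 RPKM, was the only trans-encoded member. PP_nc715 was at 20.6 RPKM at P5 and 42.0 at P3, against 7.95 at S, and its log2 fold change at P5 of 1.27 was 0.98, under 2-fold, with a pseudocount of 5, 1.47 with median-of-ratios scaling and 2.35 with quantile normalisation. PP_nc715, PP_nc406 and PP_nc180 were the 3 higher at P3.

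**Figure D3:**
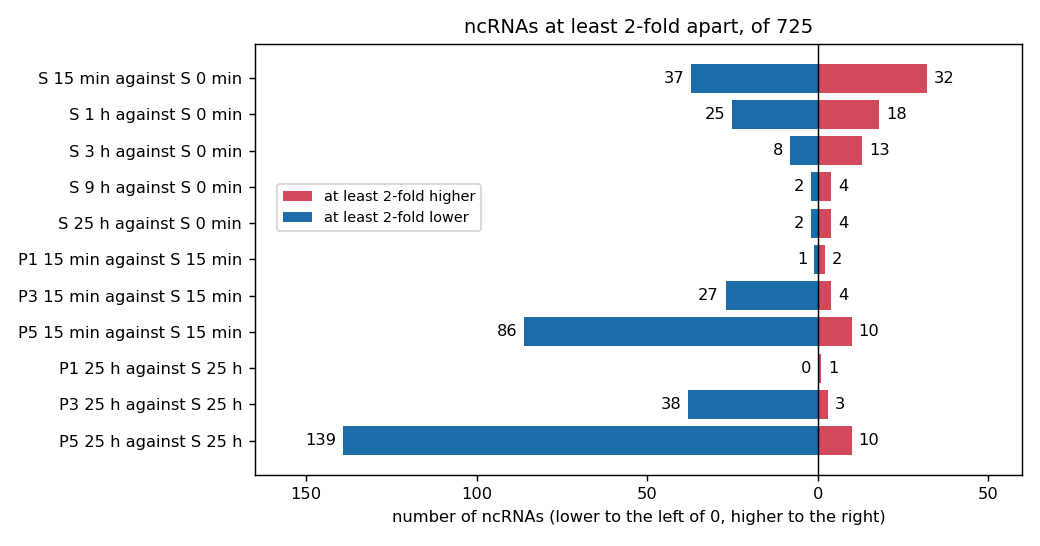
Number of the 725 ncRNAs at least 2-fold higher (right of 0) or lower (left of 0) in each of 11 comparisons, on the log2(RPKM + 1) scale of the authors' group values. Counts at S go from 69 at 15 min to 6 at 25 h, and counts at the ports from 3 at P1 to 96 at P5 at 15 min and from 1 to 149 at 25 h.

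Most of the ncRNAs lower at P5 also stepped down through the ports in order. Of the 86 lower at P5 at 15 min, 64 had RPKM values that decreased at every step from S through P1 and P3 to P5, and of the 139 at 25 h, 108 did. These sets were chosen on their end points, so only the order of P1 and P3 inside is open. P1 and P3 both lay between S and P5 for 69 of the 86 and 115 of the 139, and in 64 and 108 of these P1 was the nearer to S, where a chance order gives 50%. The median log2 fold change of the 86 was -0.22 at P1, -0.65 at P3 and -1.37 at P5, and that of the 139 was -0.16, -0.63 and -1.44. Of the 10 higher at P5, only 3 stepped up throughout at 15 min, and 7 did at 25 h. All 27 ncRNAs lower at P3 at 15 min were among the 86 lower at P5, and 37 of the 38 at 25 h among the 139; independent lists would share 3.2 and 7.29. Within a time these comparisons share the S column, and part of the overlap may come from it.

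The differences at P5 were compared between 15 min and 25 h, which share no column. Lower at both times were 82 ncRNAs, of the 86 and 139, where independent lists would share 16.5. With median-of-ratios scaling 64 of the 82 were still at least 2-fold lower at both times, and with quantile normalisation 41. The median log2 fold change of the 82 was -1.41 at 15 min and -1.98 at 25 h. It was -1.27 and -1.77 with median-of-ratios scaling, and -1.06 and -1.23 with quantile normalisation. Higher at both were 6 of the 10 and 10, where independent lists would share 0.14. These 6 were PP_nc715, PP_nc180, PP_nc406, PP_nc598, PP_nc597 and PP_nc248, of which PP_nc597 and PP_nc598 are neighbours and may not be separate entries. No ncRNA was at least 2-fold higher at one time and at least 2-fold lower at the other. Across the 725 ncRNAs, which are not independent replicates, the log2 fold changes had a Pearson r of 0.93 and a Spearman rho of 0.90, and 625 had the same sign.

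**Figure D4:**
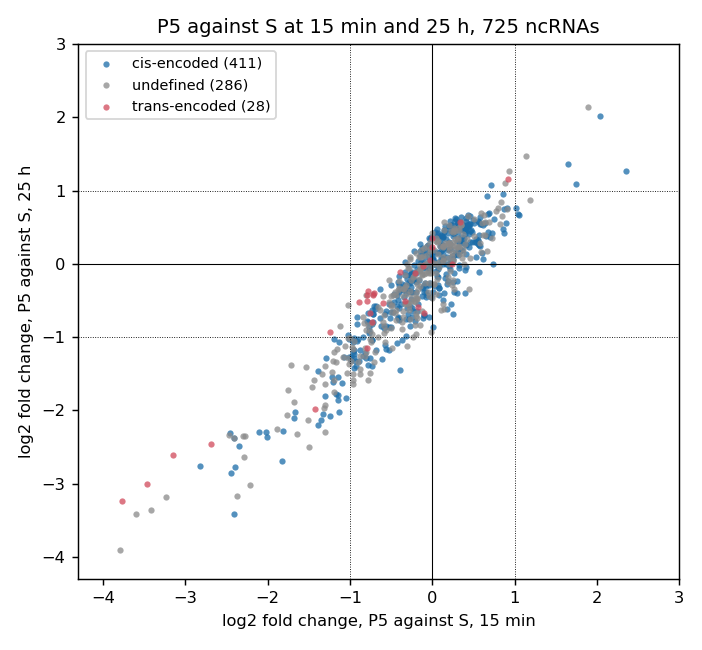
Log2 fold change of P5 against S at 15 min (x axis) and at 25 h (y axis) for 725 ncRNAs, 1 point each, coloured by the authors' class; dotted lines mark 2-fold. The points run along the diagonal (Pearson r = 0.93 across ncRNAs), with 82 at least 2-fold lower and 6 at least 2-fold higher at both times as deposited.

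Few ncRNAs differed by at least 1 in log2 in their port values between the times. In 11 of them the log2 fold change of a port against S was lower by at least 1 at 25 h than at 15 min, and in none was it higher by as much; with quantile normalisation the numbers were 10 and 1. In 8 of the 11 this was at P1 and in the other 3, PP_nc190, PP_nc316 and PP_nc715, at P5. PP_nc629 (cis-encoded, 5398094 to 5398340, minus strand) had the largest difference, -1.34, with 99.0 RPKM at P1 against 60.3 at S at 15 min and 62.2 against 96.8 at 25 h. PP_nc480 and its neighbour PP_nc481 (4413448 to 4414530, minus strand), PP_nc309 and PP_nc489 followed, at -1.25, -1.23, -1.14 and -1.10. Averaged over the 4 positions, 25 h was at least 2-fold above 15 min for PP_nc627, PP_nc597 and PP_nc667, with log2 fold changes of 1.35, 1.22 and 1.17, and at least 2-fold below for PP_nc364 and PP_nc604, at -1.18 and -1.06.

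The authors' classes were compared with random lists of the same size matched on mean expression but not on length. Trans-encoded ncRNAs were shorter, with a median length of 182.5 bases against 279 for all 725. Whether length bears on their medians was not tested. Trans-encoded ncRNAs had a median log2 fold change of -0.40 at P1, -0.36 at P3 and -0.72 at P5 at 15 min, and 24 of the 28 lay below 0 at P5. The median at P5 was -0.57 with median-of-ratios scaling and -0.35 with quantile normalisation. Of 10000 random lists of 28 ncRNAs, 0, 0 and 11 had medians as low. PP_nc202, PP_nc026, PP_nc604, PP_nc028, PP_nc651 and PP_nc465 were the 6 trans-encoded ncRNAs at least 2-fold lower at P5. At 25 h the median at P1 was -0.05, with 15 of 28 below 0 and 289 of 10000 random lists as low, and at P3 -0.32, with 45 lists as low, though with quantile normalisation 7.5% of 2000 lists were lower at P3. The 25 h median at P5 was -0.51, and 580 of 10000 random lists were as low, inside the middle 95% of the lists; under quantile normalisation that median was 0.14. The percentile describes these group values and is not a test across replicates, and 33 such class comparisons were made. Of the 18 at the ports 16 lay outside the middle 95% of the lists. They are not separate results, because the classes together make up all ncRNAs and the ports of a time share its S column. At P1 25 h cis-encoded (median 0.0115, percentile 97.6) and undefined ncRNAs (-0.0058, 2.45) lay barely outside. Over the alternatives, with 2000 lists, these percentiles ranged from 93.15 to 97.3, inside the middle 95%, and from 2.05 to 3.1. That of undefined ncRNAs at P1 15 min ranged from 0.5 to 4.1. Of the 15 over time at S 4 lay outside. Those 4 were small in size: cis-encoded ncRNAs at 9 h (median 0.14, percentile 99.83) and 25 h (0.07, 99.59), undefined ones at 9 h (0.06, 0.58) and trans-encoded ones at 25 h (-0.09, 2.31).

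Trans-encoded PP_nc027, PP_nc090, PP_nc105, PP_nc203 and PP_nc367 are uncertain as separate entries. They are 141 or 142 bases long, all on the minus strand, and their RPKM values ran together in each group, for example 86.6 to 99.0 at S 15 min, 105 to 113 at P3 15 min and 36.7 to 41.4 at P5 25 h. Their profiles, centred on their means, differed by less than 0.2 in log2 in every group. Another 12 pairs of ncRNAs of like length met the same limit, none of them in a group of 5. Whether the 5 share reads as near-identical copies was not checked, since no genome sequence was used here. Counted as 1 ncRNA, they left 24 trans-encoded ncRNAs with medians of -0.40, -0.48 and -0.49 at P1, P3 and P5 at 15 min, and at P5 1.55% of 2000 matched lists were lower. At 25 h the medians of the 24 were -0.19, -0.49 and -0.53, and 0.0%, 0.1% and 6.85% of lists were lower. The small P1 median at 25 h over all 28, -0.05, thus depends on how these 5 are counted.

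Cis-encoded ncRNAs had medians close to S at P5, -0.02 at 15 min and -0.07 at 25 h, and both medians were above 0 with median-of-ratios scaling (0.12 and 0.14) and with quantile normalisation (0.19 and 0.21). Relative to the median of all ncRNAs they lay 0.09 and 0.11 higher. Undefined ncRNAs had medians of -0.19 and -0.31, which quantile normalisation moved to 0.02 and 0.01, and lay at -0.08 and -0.13 relative to all. Lower by at least 2-fold at P5 at both times were 35 of 411 cis-encoded (8.5%), 5 of 28 trans-encoded (17.9%) and 42 of 286 undefined ncRNAs (14.7%). The numbers were 26, 5 and 33 with median-of-ratios scaling and 18, 4 and 19 with quantile normalisation.

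**Figure D5:**
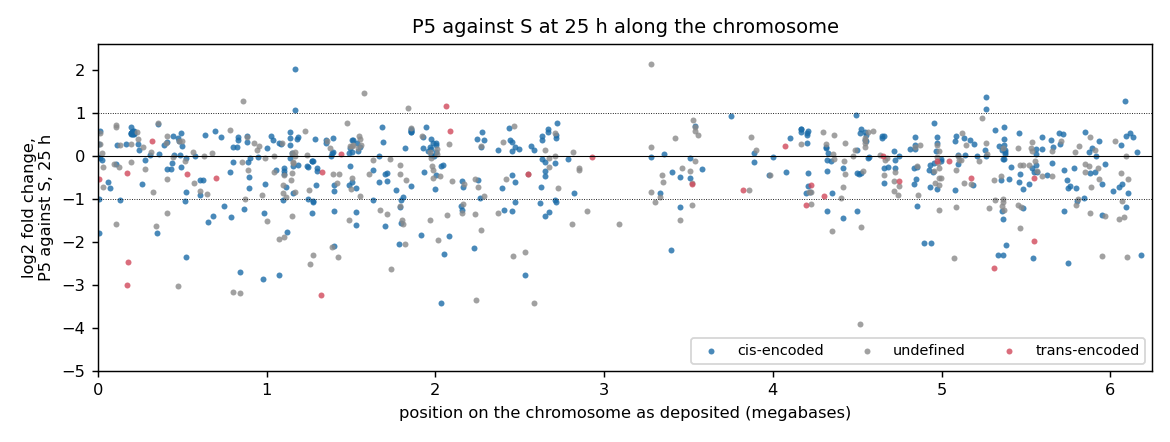
Log2 fold change of P5 against S at 25 h (y axis) against the middle of each ncRNA on the chromosome in megabases, as deposited (x axis), 1 point per ncRNA, coloured by the authors' class; dotted lines mark 2-fold. The 139 lower ncRNAs lie along the whole range, with PP_nc493 lowest at -3.90 and PP_nc406 highest at 2.14.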

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

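The pairs of later S columns, the size counts over several columns and the single count of 5 ncRNAs with 1 shared profile were chosen after seeing the data; the other alternatives were listed beforehand. No paired analysis was possible because each group has 1 value and the columns carry no replicate letter. The count-based tests and normalisations, the replicate block, the omission of replicates, the fit of only the groups compared, the estimated correlation and the distance to neighbouring genes could not be run for the same reason or for want of an annotation of this strain. Removing the filter, or raising it to a mean of 5 RPKM, left the same 725 ncRNAs and so says nothing about stability. The 16 counts of ncRNAs at least 2-fold apart were within 1.5 times the main count with pseudocounts of 0.1 and 5 and with median-of-ratios scaling. With quantile normalisation 13 were, and P3 25 h went from 41 to 24, P5 25 h from 149 to 95, and any port at 25 h from 150 to 95; the cause was not tested. The share of lower calls among those at any port moved from 88.7% to 77.5% (median-of-ratios) and 66.7% (quantile) at 15 min, and from 93.3% to 73.7% (quantile) at 25 h. The 124 named values were chosen for their size, so that none changed sign says little. Over the 4 alternatives that can move them, 331 of 496 values moved by less than the SD of S 25 h against S 9 h (0.12), the smallest of the 3 later S spreads, and 420 by less than the widest (0.23). In all 9 named values fell under 2-fold in at least 1: 7 with a pseudocount of 5, 4 with quantile normalisation and 1 with median-of-ratios scaling. The largest move was 1.5 in log2, for PP_nc358 at P5 15 min, from -2.47 to -0.97 with quantile normalisation. As the lowest value of its group it was replaced there by the mean of the group minima. The other 8 were within 0.3 of the limit before. Class medians changed sign in 7 cases: cis-encoded at P5 to 0.122 (15 min) and 0.137 (25 h) with median-of-ratios scaling, and with quantile normalisation cis-encoded to 0.186 and 0.21, undefined to 0.016 and 0.014, and trans-encoded at 25 h to 0.144. The medians of all ncRNAs moved with them, to 0.04 and 0.03 or 0.10 and 0.13, which accounts for the cis-encoded and undefined changes, since relative to all ncRNAs these classes kept their side. Trans-encoded ncRNAs at P5 25 h went from -0.33 to 0.01 relative to all. The percentile of trans-encoded ncRNAs among matched lists at P5 15 min ranged from 0.05 to 1.55 over the alternatives and that at P5 25 h from 5.65 to 40.05; quantile normalisation moved that at P3 25 h to 7.5. Mapped depth is unknown. If all of the nominal 20M reads entered the total, PP_nc358 at P5 15 min would rest on about 11.3 reads in each of 3 libraries. At S 15 min it would rest on 86.9 in each. Relative counting error is thus largest for the lowest values, and its size for a group value that combines 3 libraries is unknown.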

Other observations

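The tests of the shared S 15 min column, of a removed length trend, of quantile normalisation on the 82 ncRNAs and of shared profiles were chosen after the result was seen, and the others before. Most ncRNAs at least 2-fold higher at S 15 min than at 0 min were lower at P5. The reverse could not hold at that size, because only 32 ncRNAs were at least 2-fold higher at S 15 min. Of these 32, 21 were among the 82 ncRNAs at least 2-fold lower at P5 at both times. Of the 82, 74 lay above 0 at S 15 min. Of the 32 ncRNAs higher at 15 min, 22 were at least 2-fold lower at P5 25 h, where independent lists would share 6.1, and their median log2 fold change there was -1.89. Of the 37 lower at 15 min, 0 were, where 7.1 would be shared, and their median was 0.14. PP_nc118 was at 426 RPKM at 0 min, 1330 at S 15 min, 824 at S 25 h and 89.3 at P5 25 h, and PP_nc026, PP_nc604 and PP_nc364 had the same course. PP_nc597, PP_nc598 and PP_nc406 went the other way, higher at S 15 min and higher again at P5. A shared S 15 min column could give such a relation, but the Spearman rho across ncRNAs was -0.444 between S 15 min against 0 min and P5 25 h against S 25 h, which share no column. A biological difference between the positions and times, which the design names, stays open and was not tested.

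The 82 ncRNAs at least 2-fold lower at P5 at both times were weighed against technical explanations. A few abundant RNAs taking more reads would lower all others by 1 factor; after median-of-ratios scaling 78.0% (64 of 82) were still at least 2-fold lower at both times, and their 25 h median moved from -1.98 to -1.77. Quantile normalisation, which forces equal distributions, left 41 at that size and 81 below 0. The log2 fold change had a Spearman rho with length of 0.123 at 15 min and 0.079 at 25 h. The 15 min rho exceeded the limit set beforehand for setting length aside, so that planned test left length undecided. After the medians of 5 length groups were removed 91.5% stayed lower. Those medians ran only from -0.35 to -0.003 at 25 h, a small trend beside 2-fold, so their removal could hardly undo the pattern. The rho with distance from position 1 was -0.049. The median of the 82 ncRNAs' mean RPKM, 114.3, lay above the lower quartile of all, 84.7, although 24 of the 82 were below it. The tables thus argue against read share and a gradient with distance from position 1, each as the whole cause, and leave length undecided. Other effects of position were not tested by that rho. A low mean RPKM was not the whole cause either, but that mean covers all 12 groups, so low values at P5 itself were not tested. Differences in handling between positions and a biological difference between positions stay open, as the design gives no test of either without values per library.

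At S 69 ncRNAs were at least 2-fold from 0 min at 15 min and 6 at 25 h, although single ncRNAs went the other way: PP_nc597 and PP_nc598 were furthest from 0 min at 25 h, and PP_nc343 and PP_nc406 at 3 h. If the 0 min column alone were out of place, 15 min and 25 h would lie level. The 66 ncRNAs chosen only for being at least 1.5-fold higher at 1 h than at 0 min had a median log2 ratio of 15 min to 25 h of 0.303. The quartiles were 0.10 and 0.62, and 54 of the 66 were above 0. For ncRNAs that were higher after 0 min this argues against that explanation as the whole cause. The ncRNAs lower after 0 min were not tested in this way. A passing difference between 15 min and later times may remain as a hypothesis.

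A hypothesis that some neighbouring entries are parts of 1 transcript was tested at P5 25 h. Over 140 pairs of same-strand neighbours less than 500 bases apart, the median absolute difference in log2 fold change was 0.241, against 0.704 for random pairings, and 0 of 10000 sets of random pairings were as small. Over 22 such pairs on opposite strands it was 0.798, and 68.4% of random sets were as small. The values are consistent with shared transcripts or shared control among same-strand neighbours, which this test does not separate, and such neighbours are then not independent entries. A second hypothesis, that abundant ncRNAs keep their level at P5 while rare ones do not, was not borne out: the Spearman rho of the log2 fold change with mean RPKM was 0.076 at 15 min and 0.034 at 25 h.

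The 5 like-sized trans-encoded ncRNAs described above differed from each other by at most 0.11 in log2 in any group once each was centred on its mean, and by at most 0.30 without centring. The nearest other ncRNA was 0.24 away. They were highest at P3 15 min, at 105 to 113 RPKM, whereas trans-encoded PP_nc202 was at 782 RPKM at S 15 min and 192 at P3 15 min. Of the 725 entries 4 pairs of neighbours overlapped, 3 of them on opposite strands, and whether counting used strand is not given in the sources used here, so the values of these pairs are uncertain. The same gap bears on any ncRNA that overlaps an annotated gene on the other strand. How many do, among the 411 cis-encoded ones or the rest, was not checked for want of an annotation of this strain.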
